A study of Homo sapiens with 31 samples.

How the data were processed

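Total RNA of Caco-2 cells was profiled on an Affymetrix whole-transcript array, with 100 ng of RNA labelled per sample, per the labels' protocols. The platform name and array annotation used by the authors, and any genome build, are not given in the sources used here. Cells of passage 29 to 45 were seeded at 75000 cells per cm2 and kept for 21 days. The chip was perfused at 100 µL/h with a shear stress of about 0.002 dyne/cm2, per the labels' protocols. During exposure the upper chamber of the chip was filled over about 42 min and the flow was then stopped for the 6 h, whereas Transwell inserts received 500 µL of suspension. The labels place 4 arrays in each of 7 groups and 3 in the Transwell TiO2 group. Each nanomaterial had its own metal-free control medium in each system.

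The values were deposited by the authors on the log2 scale, and they were normalised with RMA, per the submitters' processing notes, with its version not given in the sources used here. RMA corrects the background, quantile-normalises the arrays and summarises probes per probe set, which makes the arrays comparable in overall distribution and could hide a shift common to all genes. The value table held 53617 probe sets on 31 arrays with 0 missing values and values from 0.3615 to 13.5. The scale was checked against the values. All 31 columns were matched to samples by title, with 0 columns left unmatched, and 0 columns were identical to another. Correlations between arrays ran from 0.9515 to 0.9927.

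Probe sets were named from the platform annotation supplied with the series. Of the 53617 probe sets 23871 named 1 gene, 1842 named several and 27904 had no gene listed. Names were taken only from probe sets with 1 gene. Symbols were updated through the gene identifier with the RefSeq gene table of GRCh38.p14, which matched 21171 of them, and no coordinates were used. For the 632 genes with several probe sets the one with the highest mean over all arrays was kept, which left 22395 genes, and values are therefore 1 per gene. Metallothionein paralogs are nearly identical in sequence, so values of single members are uncertain because probes can bind more than 1 of them.

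Differences were tested with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 8 groups, so that every comparison shared one estimate of the spread with 23 residual degrees of freedom, and the empirical Bayes prior had 4.77 degrees of freedom. P-values were adjusted with the Benjamini-Hochberg method over all 22395 genes within each comparison, and the threshold was an adjusted p below 0.05. The comparisons were each exposure against its own control in each culture system, the difference of these responses between the systems, chip against Transwell in control media as the mean over both media, and the ZnO control medium against the TiO2 control medium as the mean over both systems. Comparisons by single medium or single system were contrasts of the same fit. Of these only the counts of genes for chip against Transwell in each control medium were planned, and the list tests by medium, all tests of the control media by system and the correlations other than that of the ZnO responses were chosen after seeing the data. Responses set side by side had separate control arrays.

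The gene lists numbered 25 and covered metallothioneins, zinc transporters, heat shock proteins and chaperones, NRF2 targets, the unfolded protein and integrated stress response, immediate early genes, NF-kB and inflammatory genes, hypoxia-inducible genes, cholesterol synthesis, fatty acid oxidation, enterocyte markers, drug metabolism, aryl hydrocarbon receptor targets, cell junctions, proliferation, p53 targets, mucus and secretory markers, stem and progenitor markers, YAP targets, extracellular matrix, interferon-stimulated genes, iron handling, the nuclear-encoded respiratory chain, stromal and immune cell markers, and mitochondrially encoded genes. Of the last list 0 members were measured by a probe set with 1 gene, so it could not be tested. Each list was tested with camera at a preset correlation between genes of 0.01, with the Benjamini-Hochberg adjustment over the 24 lists of a comparison. Camera with a correlation estimated per list and fry were the alternatives. Some genes are members of several lists, such as ATF3 and SESN2.

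The choices of groups, tests, lists, alternatives and of genes to name were otherwise made before the data were examined. Named genes were, per comparison, up to 10 with the largest rise and up to 10 with the largest fall among those that passed and whose replicates did not overlap between the groups, the overlap condition being dropped for response differences and control media. To these were added up to 4 members with the smallest p of each list described, and, where fewer than 5 genes passed, the 5 with the smallest p. Genes named in one comparison were also given in others.

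The alternatives were an intensity trend or a robust prior, array weights, leaving out the lowest 30% of probe sets by mean, keeping probe sets above log2(20) on at least 4 arrays, quantile normalisation or median centring of the deposited values, a deposit batch of 7 arrays against 24 inferred from the order of submission, the replicate number as a block, every probe set in place of 1 per gene, a 1.5-fold minimum, an unadjusted p under 0.01, the compared groups alone, and leaving out each array in turn. Fits with arrays of the same culture system alone and with 1 array weight per culture system were added after seeing the data, because chip replicates spread more than Transwell replicates, as were fits without both chip arrays of a nanomaterial that lay apart. The deposit batch as a term had 0 genes that passed.

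The steps were tested on simulated data with 200 changed genes among 22395 and the spread of each gene within each culture system, before use on the deposited values. The share of genes that passed falsely was 7.02% for Transwell ZnO, 19.8% for chip ZnO, 10.2% for the difference in ZnO response, 3.77% for Transwell TiO2, 20.7% for chip TiO2, 4.95% for the difference in TiO2 response, 3.87% for the culture comparison and 7.33% for the control media. For the differences in response 53.8% of 2-fold changes were recovered with ZnO and 43.5% with TiO2. The adjustment is less strict with 200 changed genes than with few. Shares recovered are therefore likely too high for comparisons where few or 0 genes passed. Shares of false calls may be higher there, because fewer true changes would stand beside the false ones. The chip was simulated with its own spread but tested with an estimate shared with Transwell, whose replicates spread less. In the simulation of chip ZnO 0 of 24 unchanged lists passed, and 1 of 1 list of 20 genes shifted by 0.5 log2 did. The simulated genes varied independently, so this cannot show how often correlated lists pass falsely at the preset correlation. The estimated correlation of the proliferation genes, for example, was 0.522. Figures were drawn with matplotlib 3.10.9.

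The labels do not state whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Depth does not apply to arrays, and the number of arrays per group limits the precision.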

Results

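Gene expression was measured in Caco-2 cells, a human colorectal adenocarcinoma line that forms a polarised, enterocyte-like monolayer when kept confluent. The cells were grown for 21 days either without flow on Transwell inserts or in a microfluidic gut-on-chip under continuous flow of 100 µL/h. They were then exposed for 6 h to titanium dioxide (TiO2) or zinc oxide (ZnO) nanomaterial, or to the matching metal-free dispersion medium as control. Transwell cultures received 50 µg/mL TiO2 or 10 µg/mL ZnO, and chip cultures received 100 µg/mL TiO2 or 80 µg/mL ZnO. Per the labels, these doses were modelled to give equal deposited doses in both systems. The 31 arrays formed 8 groups, with 4 arrays in each group except Transwell TiO2, which had 3. Values were on the log2 scale and ranged from 0.3615 to 13.5, and the array medians lay between 3.243 and 3.333. Signal over background was not used. A gene whose group mean lay below the median of every array of that group was therefore not shown to be above background there, and the size of its difference from a brighter group is a lower bound at best. The number of arrays limited the precision of every comparison. In the text below a gene or list is said to have passed when its Benjamini-Hochberg adjusted p was below 0.05. Errors of log2 differences are standard errors from limma with n = 4 arrays per group, or n = 3 for Transwell TiO2.

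The culture system separated the arrays more than any exposure did. The first principal component held 42.4% of the variance, and all chip arrays lay on one side of it and all Transwell arrays on the other. Chip replicates also spread more than Transwell replicates. Over the 11200 brighter genes the root mean within-group variance was 0.289 in the chip and 0.186 in Transwell, a ratio of 1.56. The second component (7.76%) separated the 2 nanomaterial sets in Transwell, exposed and control arrays alike. The Transwell TiO2 set lay at 16.8 to 29.1 and the Transwell ZnO set at -27.7 to -9.83. The chip ZnO set lay at -10.0 to 4.84. On this component chip TiO2 replicate 4 at -15.4 and chip TiO2 control replicate 4 at -9.37 lay apart from the other chip arrays of the TiO2 set. On the third component (4.45%) TiO2 replicate 4 at -14.0 lay near the other chip TiO2 controls (-19.4 to -14.9). Control replicate 4 at 7.81 lay on the side of the other chip TiO2 arrays (16.7 to 20.1).

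**Figure D1:**
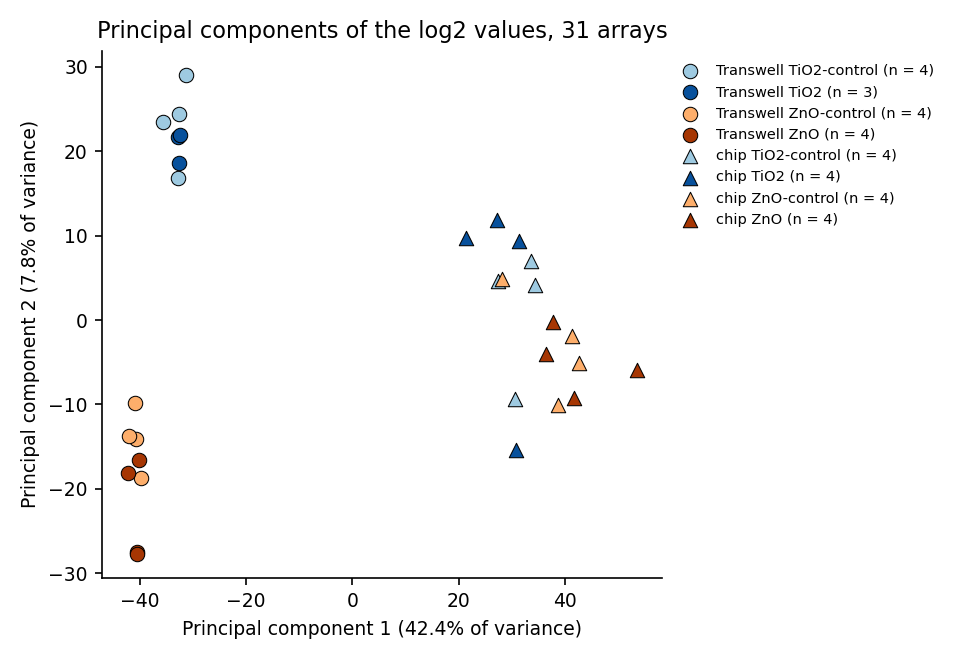
Principal components 1 and 2 of the log2 values of all genes tested, 1 point per array, with circles for Transwell and triangles for chip and colours for the 4 exposures and media. The first component (42.4% of the variance) separates the culture systems. In Transwell the second (7.76%) separates the TiO2 set, exposed and control, from the ZnO set. In the chip it separates TiO2 replicate 4 and TiO2 control replicate 4 from the other TiO2-set arrays.

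The first comparison asked how unexposed cells in the chip differed from those in Transwell, over both control media. Enterocyte markers were lower in the chip as a set, and YAP targets, immediate early genes and extracellular matrix genes were higher. The enterocyte call was lost with an estimated correlation (adjusted p = 0.124) and the other 3 were kept. CYP7A1, the rate-limiting enzyme of bile acid synthesis, was lower by a log2 difference of -4.82 ± 0.12 (adjusted p = 1.55e-21), from 7.13 ± 0.31 and 7.23 ± 0.22 (SD, n = 4) in the Transwell TiO2 and ZnO control media to 2.30 ± 0.18 and 2.42 ± 0.20 in the chip. FABP2, the intestinal fatty acid binding protein, was lower by -4.25 ± 0.17, G6PC1, the glucose-6-phosphatase of gluconeogenesis, by -3.90 ± 0.24, and CPS1, the first enzyme of the urea cycle, by -3.85 ± 0.29. In the chip control media CYP7A1, FABP2 (2.20 ± 0.41 and 2.05 ± 0.53) and G6PC1 (3.28 ± 0.62 and 3.05 ± 0.62) read below the array medians. In the other direction PLAUR, the urokinase receptor, was higher by 3.89 ± 0.15 (adjusted p = 3.09e-17), ANXA1, a phospholipid-binding protein active in inflammation and epithelial repair, by 3.11 ± 0.13 and ANKRD1, a target of the mechanosensitive coactivator YAP, by 2.90 ± 0.18.

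In total 7495 of 22395 genes (33.5%) passed, 3260 higher and 4235 lower in the chip. At least 2-fold differences were found in 544 of the higher and 678 of the lower genes. The other leading genes higher in the chip were MT1G (3.74), MT1H (3.66), UPK1B (3.54), BNIP5 (3.09), DHRS2 (3.06), EMP3 (3.05) and QSOX1 (2.96). Leading genes lower in the chip included ASAH2C (-4.25), C17orf78 (-4.04), the phosphate and urate transporter SLC17A4 (-3.90), the steroid-conjugating UGT2B17 (-3.83), ADGRG7 (-3.81) and AGMO (-3.65). Of these, C17orf78 (3.26 and 2.54) and UGT2B17 (2.90 and 2.77) also read below the array medians in the chip control media. When each control medium was taken alone, 5127 genes passed in the TiO2 control medium and 6101 in the ZnO control medium. Of these, 1382 were higher and 1959 were lower in both, against 259 and 451 for independent lists. The differences in the 2 media correlated across genes with r = 0.75 and rho = 0.579, and genes are not independent replicates.

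Among 28 enterocyte and brush border markers, 20 were lower and 3 were higher in the chip (21 and 4 adjusted over the list alone). The lower members included FABP2, the glucose transporter SLC5A1 (-1.63 ± 0.10), the fructose transporter SLC2A5 (-1.95 ± 0.15) and sucrase-isomaltase, SI (-3.36 ± 0.33). The limma set test camera placed the list below other genes (adjusted p = 4.22e-08), and this was not kept with an estimated correlation (adjusted p = 0.124). Stem and progenitor markers were also lower, 11 of 15 with 1 higher (11 and 2 adjusted over the list alone), among them LRIG1 (-0.71), RNF43 (-0.81), SOX9 (-0.87) and ZNRF3 (-0.98). Their list had a camera adjusted p of 8e-04 (adjusted p = 0.0919 with an estimated correlation).

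YAP targets and mechanosensitive genes were higher in the chip for 13 of 19 members and lower for 1 (14 and 1 adjusted over the list alone), with camera adjusted p = 4.22e-08 and adjusted p = 0.00144 with an estimated correlation. Besides ANKRD1 these included NPPB (2.13), CCN1 (2.57) and TAGLN (1.15). Extracellular matrix and adhesion genes were higher for 17 of 24 and lower for 2 (17 and 2 adjusted over the list alone), including ITGB4 (1.71), TGFB1 (1.23), LAMB1 (0.94) and the epithelial metalloprotease MMP7 (2.83, from below the array medians in Transwell). That list passed with the preset correlation (adjusted p = 2.96e-08) and with an estimated correlation (adjusted p = 0.0122). Immediate early genes, which are induced within minutes to hours of a stimulus, were higher for 17 of 21 (18 higher and 1 lower adjusted over the list alone), for example DUSP5 (2.65), ZFP36 (1.77) and JUNB (1.75). Their adjusted p was 1.79e-15, and 0.00173 with an estimated correlation. Targets of the aryl hydrocarbon receptor were higher for 6 of 8 (6 adjusted over the list alone), led by the xenobiotic oxidase CYP1A1 (2.55 ± 0.12), LMCD1 (1.72), TIPARP (1.28) and CYP1B1 (0.89, from below the array medians in Transwell). This list had adjusted p = 2.4e-05 and adjusted p = 0.00144 with an estimated correlation.

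Several stress lists were higher in the chip over both media. The unfolded protein and integrated stress response had 16 of 24 members higher and 1 lower (16 and 1 adjusted over the list alone), with ATF3 at 2.43, DDIT3 at 1.99, PPP1R15A at 1.81 and TRIB3 at 1.03. Camera gave adjusted p = 1.36e-07, and adjusted p = 0.0122 with an estimated correlation. Heat shock proteins and chaperones had 10 of 16 higher and 2 lower (11 and 2 adjusted over the list alone), including CRYAB (2.74), HSPB1 (1.81) and HSPB8 (1.68, from below the array medians in Transwell), with adjusted p = 7.06e-05 and adjusted p = 0.194 with an estimated correlation. NRF2 antioxidant targets had 15 of 26 higher and 4 lower (16 and 4 adjusted over the list alone), among them thioredoxin reductase TXNRD1 (1.13) and glutathione reductase GSR (0.68). Their adjusted p was 7.06e-05 (adjusted p = 0.0616 with an estimated correlation). Metallothioneins, the small cysteine-rich proteins that bind zinc and copper, were higher for 6 of 10 (7 adjusted over the list alone), with MT1X at 1.57 and MT2A at 1.32. That list had adjusted p = 9.58e-06 (adjusted p = 0.135 with an estimated correlation).

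Inflammatory and antiviral lists were higher with the preset correlation alone. NF-kB and inflammatory genes had 14 of 26 higher and 5 lower (14 and 5 adjusted over the list alone), including ICAM1 (1.89), NFKB2 (1.85), NFKBIA (1.84) and TNFAIP3 (1.58). Camera gave adjusted p = 0.00282, and adjusted p = 0.197 with an estimated correlation. Interferon-stimulated genes had 14 of 24 higher (16 higher and 1 lower adjusted over the list alone), with IFIT2 at 2.31 (from below the array medians in Transwell), IFI27 at 1.94, IRF1 at 1.89 and ISG15 at 1.16, at adjusted p = 9.58e-06 (adjusted p = 0.135 with an estimated correlation). Hypoxia-inducible genes had 14 of 29 higher and 7 lower (15 and 7 adjusted over the list alone), with ENO2 at 1.91, ADM at 1.84, SLC2A3 at 1.32 and ERO1A at 0.96, at adjusted p = 0.00902 (adjusted p = 0.431 with an estimated correlation). Over both media proliferation genes had 14 of 30 higher and 5 lower (15 and 5 adjusted over the list alone), with BUB1 at 0.77, CDC20 at 0.74, NUSAP1 at 0.72 and CCNB2 at 0.65, at adjusted p = 0.0218 (adjusted p = 0.617 with an estimated correlation).

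Some of these differences between chip and Transwell depended on the control medium, by list tests chosen after seeing the data. Heat shock genes had a mean of 1.19 in the TiO2 control medium (adjusted p = 6.57e-12, and 0.0202 with an estimated correlation) and of 0.303 in the ZnO control medium (adjusted p = 0.327), with HSPH1 at 0.68 and -0.77. The unfolded protein and integrated stress response had means of 0.77 (adjusted p = 4.39e-13, and 0.00144 with an estimated correlation) and 0.434 (adjusted p = 0.00526, and adjusted p = 0.212 with an estimated correlation). For YAP targets the means were 0.575 and 0.943, and the list passed in each medium with both correlations. The test of the difference between the media passed with an estimated correlation for heat shock genes (adjusted p = 0.0452), the stress response (adjusted p = 0.0449) and YAP targets (adjusted p = 0.0449). Proliferation genes had a mean of -0.135 in the TiO2 control medium, where 9 members were lower and 1 higher (adjusted p = 0.291). In the ZnO control medium their mean was 0.452, and 16 were higher (adjusted p = 9.46e-07, and adjusted p = 0.315 with an estimated correlation). RRM2 had differences of -0.16 and 0.66 there, and the difference of the list between the media had adjusted p = 1.22e-15 (adjusted p = 0.158 with an estimated correlation). With the preset correlation alone the media also differed for metallothioneins, with means of 1.92 and 1.06 (adjusted p = 0.000198, and adjusted p = 0.343 with an estimated correlation), and for enterocyte markers, with -0.604 and -1.18 (adjusted p = 4.3e-06, and adjusted p = 0.343 with an estimated correlation). The same held for interferon-stimulated genes, with 0.405 and 0.883 (adjusted p = 0.00201, and adjusted p = 0.467 with an estimated correlation), hypoxia-inducible genes, with 0.162 and 0.351 (adjusted p = 0.0161, and adjusted p = 0.494 with an estimated correlation), and zinc transporters, with 0.0394 and -0.156 (adjusted p = 0.0161, and adjusted p = 0.413 with an estimated correlation).

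The remaining lists held members that moved both ways, and camera did not separate them from other genes. Drug metabolism and transport had 6 of 25 higher and 13 lower (7 and 13 adjusted over the list alone, camera adjusted p = 0.0901), with CYP3A5 at 2.30 and the sulfotransferase SULT2A1 at -2.59. Zinc transporters had 5 of 21 higher and 7 lower (5 and 8 adjusted over the list alone, adjusted p = 0.449), with SLC39A4 at 0.91, SLC30A1 at 0.80 and SLC30A10 at -1.43 (to below the array medians in the chip). Iron handling had 2 of 14 higher and 7 lower (2 and 7 adjusted over the list alone, adjusted p = 0.103), with the iron importer SLC11A2 at -1.64. Cell junction genes had 7 of 24 higher and 4 lower (8 and 5 adjusted over the list alone, adjusted p = 0.126), with DSG2 at 0.78 and DSC2 at -0.59, and mucus and secretory lineage markers had 6 of 25 higher and 2 lower (6 and 2 adjusted over the list alone, adjusted p = 0.126), with TFF1 at 1.69 and ZG16 at -2.05. Fatty acid oxidation genes had 5 of 19 higher and 5 lower (6 and 7 adjusted over the list alone, adjusted p = 0.408), with PDK4 at 2.11 (from below the array medians in Transwell) and CPT1A at 1.71. Targets of p53 had 9 of 23 higher and 7 lower (9 and 7 adjusted over the list alone, adjusted p = 0.408), with PLK3 at 2.43 and TP53I3 at -1.01, and their median of -0.10 and mean of 0.22 differed in sign. Cholesterol synthesis had 6 of 19 higher and 7 lower (7 and 7 adjusted over the list alone, adjusted p = 0.971), with INSIG1 at 1.14 and LSS at -0.88, and its camera direction was downward although its median (0.03) and mean (0.01) were above 0. The nuclear-encoded respiratory chain had 5 of 27 higher and 3 lower (5 and 2 adjusted over the list alone, adjusted p = 0.317). Stromal and immune cell markers, which would rise with cells of another type, had 3 of 17 higher and 3 lower (3 and 3 adjusted over the list alone, adjusted p = 0.971), with CD68 at 0.64 and LUM at -0.98.

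**Figure D2:**
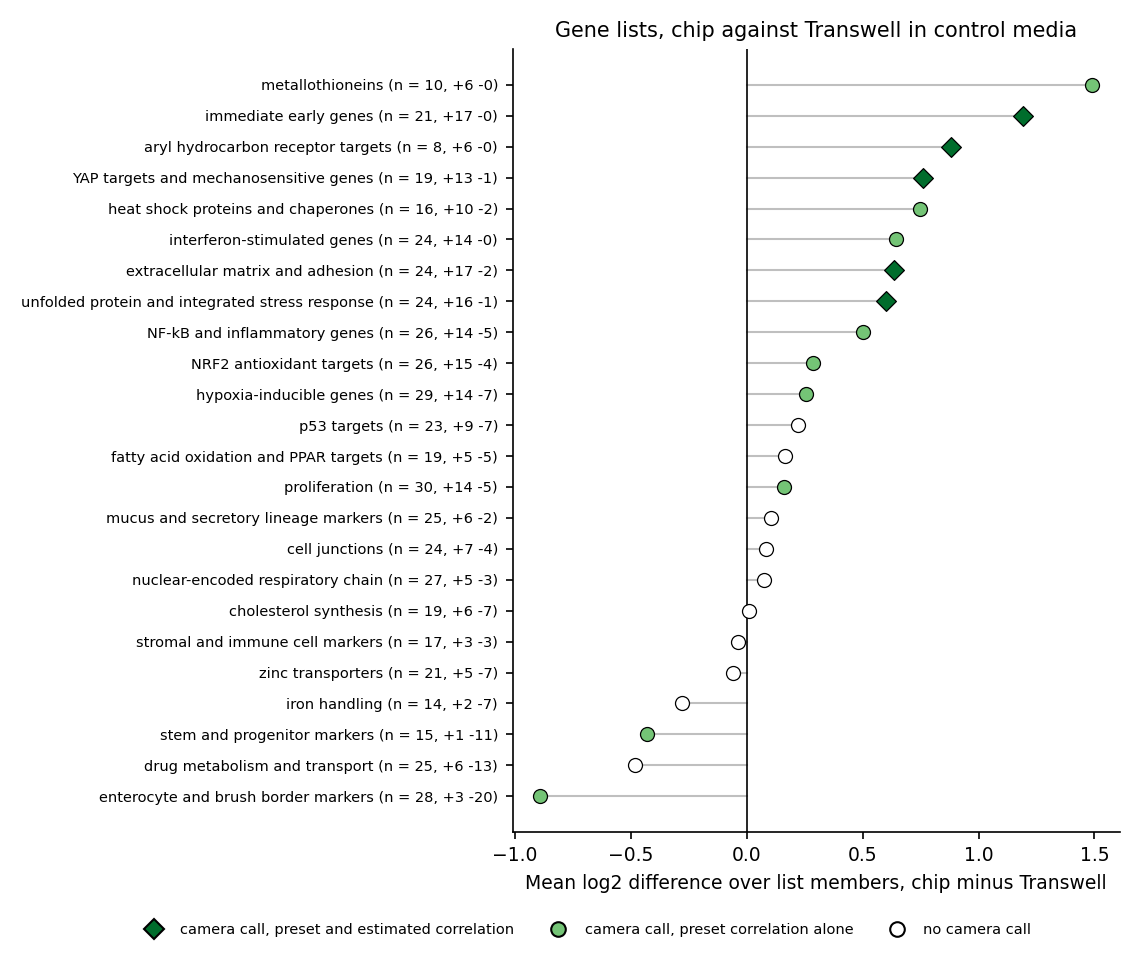
Mean log2 difference, chip minus Transwell in control media, over the members of each gene list, with the number of members and of members passing higher (+) or lower (-). Dark diamonds passed camera with the preset and an estimated correlation, light circles with the preset alone and white circles not at all, and metallothioneins lie farthest up while enterocyte markers (20 of 28 lower) lie farthest down.

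The next comparison asked what ZnO did to cells on Transwell inserts. Immediate early genes and YAP targets were higher as sets, while no single gene passed. Of 21 immediate early genes 19 had a difference above 0, with a mean of 0.248 (camera adjusted p = 2.26e-09, and 0.0293 with an estimated correlation), but 0 passed singly and 4 did so adjusted over the list alone. EGR1 had a difference of 0.68 ± 0.17, KLF6 of 0.44 ± 0.13 and JUNB of 0.42 ± 0.14, and none of these passed over all genes. For YAP targets 14 of 19 had a difference above 0, with a mean of 0.159 (adjusted p = 0.000127, and 0.0293 with an estimated correlation). ANKRD1 at 0.68 ± 0.25 and LATS2 at 0.30 ± 0.10 did not pass, and 0 members passed adjusted over the list alone. With limma's fry, which does not compare a list with other genes, adjusted p was 0.0542 for both lists. A fit of the Transwell arrays alone was chosen after seeing the data. There fry gave adjusted p = 0.00812 for YAP targets and 0.00469 for immediate early genes. In that fit 6 YAP targets and 5 immediate early genes passed adjusted over the list alone, and 0 passed singly.

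A further 3 lists passed with the preset correlation alone. Metallothioneins were above 0 for 9 of 10 members with a mean of 0.458 (adjusted p = 0.000127, and adjusted p = 0.335 with an estimated correlation), and 1 passed adjusted over the list alone. MT2A read 7.58 ± 0.18 in control and 8.10 ± 0.07 after ZnO (SD, n = 4), and MT1G read 5.97 ± 0.28 and 7.07 ± 0.22. With the spread estimated from the Transwell arrays alone, a setting chosen after seeing the data, the metallothionein list passed with an estimated correlation as well (adjusted p = 0.0187) and 6 members passed adjusted over the list alone. NRF2 targets were above 0 for 20 of 26 (adjusted p = 0.00193, and adjusted p = 0.222 with an estimated correlation), with 0 passing singly or adjusted over the list alone, and GCLM, a subunit of the enzyme that limits glutathione synthesis, had a difference of 0.44. Hypoxia-inducible genes were below 0 for 23 of 29 (adjusted p = 0.00112, and adjusted p = 0.772 with an estimated correlation), with 0 passing singly or adjusted over the list alone, NDRG1 at -0.38 and MXI1 at -0.29. Control replicate 1 stood apart in this list, at 7.477 against 7.612 to 7.631. Without it the mean was -0.167 (adjusted p = 0.000111, and adjusted p = 0.503 with an estimated correlation). The other 19 lists did not pass. The zinc exporter SLC30A1 had a difference of 0.57 ± 0.17, and the zinc transporter list had adjusted p = 0.323, with 1 member higher and 1 lower adjusted over the list alone.

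By limma 0 genes passed in Transwell ZnO, with 835 at an unadjusted p under 0.05 and 178 under 0.01, against 1120 and 224 expected from uniform p-values. Other splits of the same arrays gave a median of 119.5 genes under 0.01, so 224 is not the level of chance here. The genes with the smallest p, none of which passed, were AKR1C4 (0.86, adjusted p = 0.359), GPRC5A (0.52, adjusted p = 0.359), MIR4328 (-0.82, adjusted p = 0.445), ERC2-IT1 (-0.57, adjusted p = 0.454) and CARNS1 (-0.64, adjusted p = 0.454). MIR4328 and ERC2-IT1 read below the array medians in both groups and AKR1C4 did in control. With array weights 5 genes passed, and 6 did with 1 weight per culture system, chosen after seeing the data. Simulated 1.5-fold changes were recovered in 44.4% of genes and simulated 2-fold changes in 87.3%.

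In the chip metallothionein, heat shock, stress response and immediate early genes were higher as sets after ZnO in the fit of all arrays. MT1B rose by 5.17 ± 0.54 on the log2 scale (adjusted p = 6.76e-06), from 3.40 ± 1.56 in control to 8.57 ± 0.62 after ZnO (SD, n = 4). On 3 of the 4 control arrays MT1B read below the median of its array, so the size of its rise is a lower bound at best. MT1M rose by 4.25 ± 0.65 (adjusted p = 0.00272), from 4.88 ± 1.68 to 9.14 ± 1.22, and MT1G and MT1E rose by 2.12 ± 0.43 and 2.11 ± 0.45. The orphan nuclear receptor NR4A3 rose by 1.38 ± 0.22 (adjusted p = 0.00318), from 3.26 and so below the array medians in control, and GADD45B, which is induced by growth arrest and DNA damage, by 1.32 ± 0.21 (adjusted p = 0.00325). HMOX1, the haem-degrading enzyme of the oxidative stress response, rose by 0.92 ± 0.17 (adjusted p = 0.0183).

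Of 22395 genes 61 passed, 53 higher and 8 lower, and 44 of them changed by at least 1.5-fold. Other leading rises were RGS16, a brake on G protein signalling (1.20 ± 0.26), RAB11B-AS1 (1.11, from 2.82 in control), ZNF14 (1.08) and the stress transcription factor ATF3 (1.04 ± 0.21). All 8 genes that fell were MIR134 (-0.81), the purine synthesis enzyme PFAS (-0.75 ± 0.15), C1QL3 (-0.75, to 3.02), PRR15L (-0.69 ± 0.11), the centromere protein CENPM (-0.61 ± 0.13), HDHD5 (-0.51), the haem synthesis enzyme UROS (-0.50 ± 0.11) and POLA2, a subunit of DNA polymerase alpha (-0.49 ± 0.10).

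Metallothioneins were higher for 9 of 10 members, of which 4 passed (8 adjusted over the list alone), with a mean of 1.83 (camera adjusted p = 1.76e-15, and 0.00867 with an estimated correlation). Heat shock proteins and chaperones were higher for 16 of 16, of which 3 passed (13 adjusted over the list alone), with a mean of 0.685 (adjusted p = 2.1e-18, and 0.00867 with an estimated correlation). The 3 were the small heat shock protein HSPB8 (0.85 ± 0.19), the co-chaperone BAG3 (0.82 ± 0.17) and HSPH1 (0.77 ± 0.15), while HSPA1L at 1.00 had adjusted p = 0.053. Immediate early genes were higher for 20 of 21, of which 2 passed (12 adjusted over the list alone), namely ATF3 and the phosphatase DUSP1 (0.96 ± 0.20). The list had adjusted p = 3.07e-11, and 0.00867 with an estimated correlation, and NR4A1 at 0.94 and JUN at 0.78 did not pass.

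In the unfolded protein and integrated stress response 2 of 24 members passed (7 adjusted over the list alone), ATF3 and SESN2 (0.73 ± 0.16), and the list had adjusted p = 2.74e-07, and 0.0138 with an estimated correlation. CHAC1 at 0.82 and DDIT3 at 0.92 did not pass. Among p53 targets 1 of 23 passed, again SESN2 (4 adjusted over the list alone), and the list had adjusted p = 0.000856, and 0.00867 with an estimated correlation. CDKN1A, the cell cycle inhibitor p21, had a difference of 0.55 that did not pass. YAP targets were higher as a set (adjusted p = 0.000856, and 0.0252 with an estimated correlation), although 0 of 19 passed singly and 1 adjusted over the list alone, with LATS2 at 0.37 and THBS1 at 0.66. With the spread estimated from the chip arrays alone, a setting chosen after seeing the data, only the p53 list passed with an estimated correlation (adjusted p = 0.0485), and heat shock genes and immediate early genes had adjusted p = 0.0531, metallothioneins 0.0533, the unfolded protein list 0.0597 and YAP targets 0.0759.

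Further lists passed in the chip with the preset correlation alone. Of 21 zinc transporters 2 passed (5 adjusted over the list alone), the vesicular SLC30A2 (1.52 ± 0.30) and the plasma membrane exporter SLC30A1 (0.79 ± 0.17), with MTF1, the zinc-sensing transcription factor, at 0.43 ± 0.11. That list had adjusted p = 0.000856 (adjusted p = 0.115 with an estimated correlation). Of 26 NRF2 targets 3 passed (6 adjusted over the list alone), HMOX1, OSGIN1 (0.82 ± 0.14) and TXNRD1 (0.46 ± 0.10), with adjusted p = 0.000856 (adjusted p = 0.102 with an estimated correlation). Cell junction genes were higher as a set (adjusted p = 0.0242, and adjusted p = 0.102 with an estimated correlation), with 0 of 24 passing singly or adjusted over the list alone and CLDN4 at 0.50. The nuclear-encoded respiratory chain was lower as a set, with 22 of 27 members below 0 (adjusted p = 0.000856, and adjusted p = 0.173 with an estimated correlation), 0 passing singly and 1 adjusted over the list alone, ATP5PB having a difference of -0.34. Proliferation genes were lower as a set, with 22 of 30 below 0 (adjusted p = 0.00461, and adjusted p = 0.779 with an estimated correlation), 0 passing singly and 1 adjusted over the list alone, and thymidylate synthase TYMS had a difference of -0.55 (adjusted p = 0.0934).

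The other 13 lists did not pass in the chip after ZnO. Their adjusted p was 0.2 for stromal and immune cell markers, 0.243 for NF-kB and inflammatory genes, and 0.473 for hypoxia-inducible genes, enterocyte markers, drug metabolism, extracellular matrix and interferon-stimulated genes. It was 0.671 for cholesterol synthesis and for stem and progenitor markers, 0.698 for aryl hydrocarbon receptor targets, 0.871 for iron handling, 0.879 for fatty acid oxidation and 0.914 for mucus markers. CDX2, the intestinal identity factor, had a difference of -0.59 that did not pass (adjusted p = 0.0692).

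The count of 61 depended on the estimate of the spread and on single arrays. It was 0 when the 2 groups were fitted alone, 1 with chip arrays alone (MT1B), 15 with 1 weight per culture system, 18 with the replicate number as a block, 25 with array weights, 37 over every probe set, 159 without both ZnO replicate 1 and control replicate 4 (chosen after seeing the data), 94 without the lowest 30%, 103 with an intensity trend and 112 above log2(20). Leaving out 1 array gave 21 without control replicate 1, 9 without control replicate 3, 144 without control replicate 4, 24 without ZnO replicate 3 and 18 without ZnO replicate 4. MT1B, MT1M, NR4A3, GADD45B and PRR15L kept their calls with each of the 8 arrays left out in turn, and the other genes named as passing lost theirs without at least 1 of them. In simulated data with the spread of this comparison 19.8% of the genes that passed were false, and 50.8% of 1.5-fold and 82.4% of 2-fold changes were recovered. The simulation planted 200 changed genes, so the share false may be higher among the 61 that passed here.

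**Figure D3:**
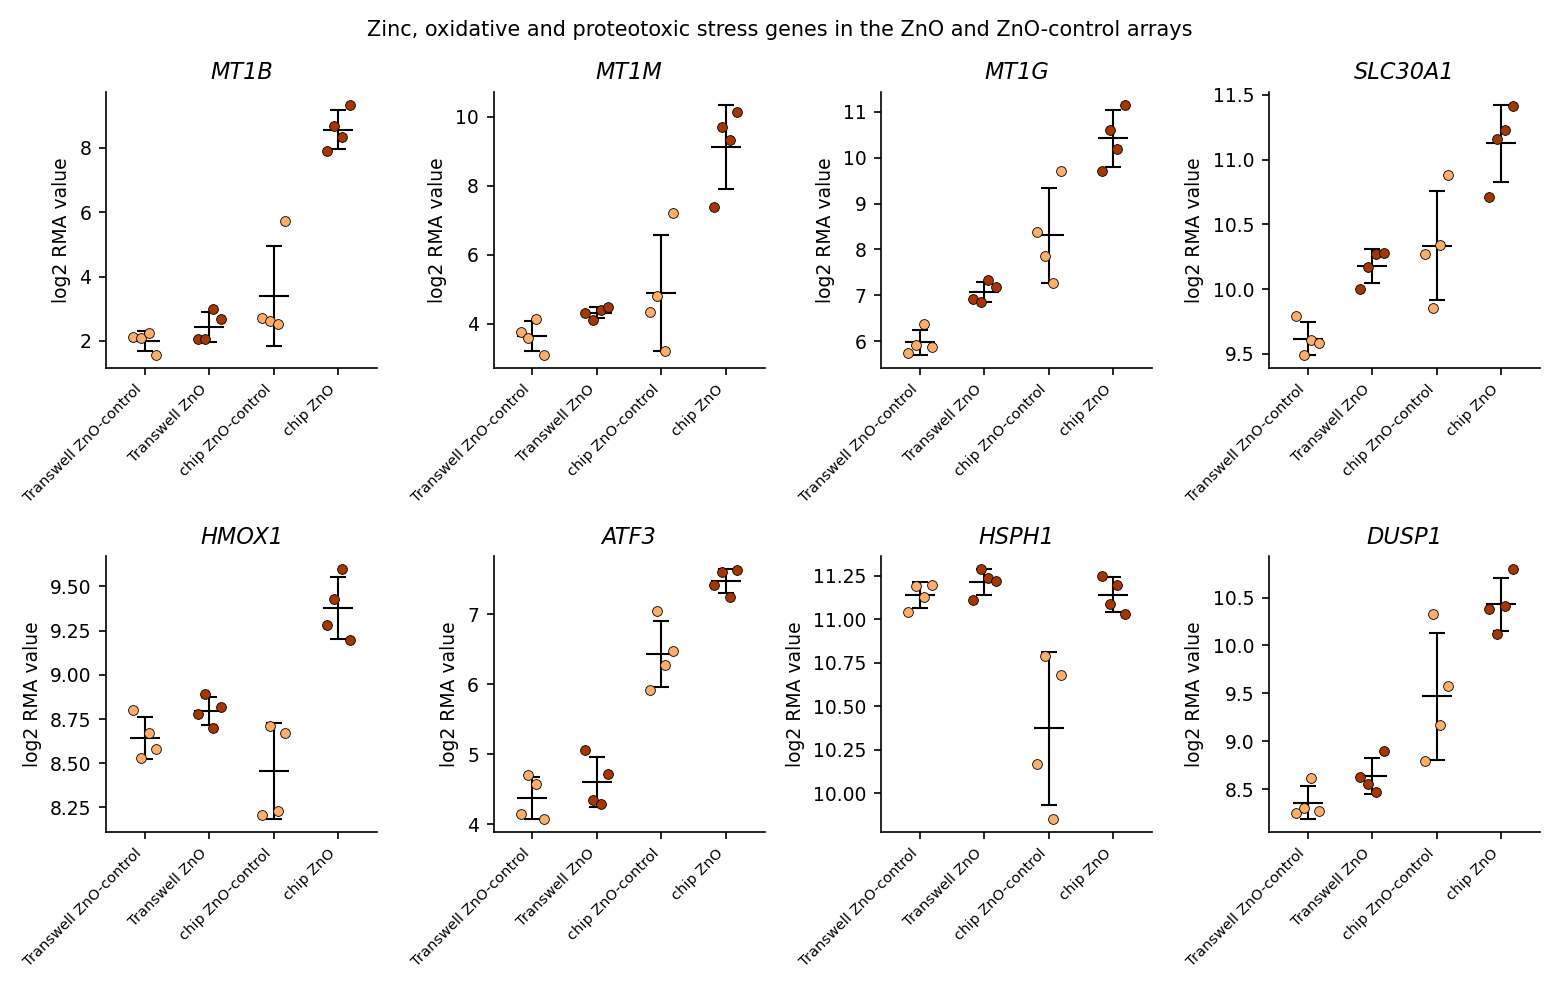
Log2 values of MT1B, MT1M, MT1G, SLC30A1, HMOX1, ATF3, HSPH1 and DUSP1 in the ZnO control and ZnO groups of both culture systems, with 1 point per array and bars for the mean ± SD of 4 arrays. MT1B rises from 3.40 to 8.57 in the chip, where the control arrays also spread widely (SD 1.56).

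The response to ZnO was then compared between the systems as a difference of differences. The ZnO concentration was 80 µg/mL in the chip and 10 µg/mL in Transwell. Effects of system and concentration therefore cannot be told apart, although the deposited doses were modelled as equal. MT1B responded more in the chip by 4.73 ± 0.77 (adjusted p = 0.0274) and was the 1 gene of 22395 that passed, with 1345 at an unadjusted p under 0.05. In Transwell MT1B read 2.00 ± 0.31 in control and 2.44 ± 0.47 after ZnO (SD, n = 4), below the array medians. It was not shown to be above background there, so the size of this difference is uncertain. MT1M (3.57 ± 0.92, adjusted p = 0.535), MT1E (1.99 ± 0.63, adjusted p = 0.692), HSPH1 (0.70 ± 0.21, adjusted p = 0.586) and SESN2 (0.73, adjusted p = 0.59) did not pass. Nor did the other genes of smallest p, NUTM2F (1.63), SIX4 (1.02), MIR378H (-1.49) and GFM1 (-0.48), each at adjusted p = 0.535.

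As sets, heat shock genes had a larger response in the chip for 16 of 16 members (adjusted p = 4.65e-10, and adjusted p = 0.0767 with an estimated correlation), with 0 passing singly and 4 adjusted over the list alone. Metallothioneins also did (adjusted p = 4e-05, and adjusted p = 0.257 with an estimated correlation), with 1 of 10 passing and 3 adjusted over the list alone. The same held with the preset correlation for the unfolded protein and integrated stress response (adjusted p = 0.00285, and adjusted p = 0.24 with an estimated correlation, 0 adjusted over the list alone) and p53 targets (adjusted p = 0.0421, and adjusted p = 0.0767 with an estimated correlation, 2 adjusted over the list alone). The respiratory chain had a more negative response in the chip for 20 of 27 members (adjusted p = 0.0395, and adjusted p = 0.712 with an estimated correlation), with 0 passing singly or adjusted over the list alone. Stromal and immune cell markers moved with these lists, with 13 of 17 above 0 (adjusted p = 0.0269, and adjusted p = 0.0767 with an estimated correlation). Of these at least COL1A2, MS4A1, CD3E and NCAM1 read below the array medians in every group and were not shown above background. Immediate early genes did not pass this test (adjusted p = 0.218).

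The MT1B call was lost when the 4 groups were fitted alone (adjusted p = 0.233), over every probe set (adjusted p = 0.121) and on leaving out any of Transwell ZnO control replicates 1, 2 and 3 (0 genes), Transwell ZnO replicates 1, 2 and 4 (0), chip ZnO control replicates 1, 2 and 3 (0) or chip ZnO replicates 2, 3 and 4 (0). Across genes the ZnO responses in both systems correlated with r = 0.0447 and rho = 0.0432, and over the 61 genes that passed in the chip with r = 0.527 and rho = 0.397, with 44 of the same sign.

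Exposure to TiO2 on Transwell inserts left no gene or list past the threshold. The genes of smallest p, none of which passed, were MRAS (0.99 ± 0.21), RN5S358 (-1.08), RN5S462 (0.96) and OR10Q1 (0.88), each at adjusted p = 0.553, and SH3D21 (-0.72, adjusted p = 0.562). RN5S358 read below the array medians in both groups, and MRAS and OR10Q1 did in control. Metallothioneins lay below 0 for 8 of 10 members with a mean of -0.265 (camera adjusted p = 0.511). With the spread estimated from the Transwell arrays alone, a setting chosen after seeing the data, that list passed (adjusted p = 0.0188, and adjusted p = 0.903 with an estimated correlation). By limma 0 genes passed, with 591 at an unadjusted p under 0.05, and array weights also gave 0. Simulated 2-fold changes were recovered in 90% of genes.

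In the chip TiO2 also left no gene past the threshold with all 8 arrays, while 7 lists moved as sets with the preset correlation alone. In this comparison TiO2 replicate 4 lay nearer to the controls on the third principal component (-14.0), and control replicate 4 (7.81) lay between the other controls and the other exposed arrays. Metallothioneins were lower for 10 of 10 members with a mean of -0.469 (adjusted p = 0.002, and adjusted p = 0.421 with an estimated correlation), with 0 adjusted over the list alone, MT1G at -1.06 and MT1X at -0.48. TiO2 replicate 4 stood apart in this list, at 6.456 against 5.645 to 5.721 in the other exposed arrays. Without it the mean was -0.661 (adjusted p = 0.000172, and adjusted p = 0.407 with an estimated correlation). Cholesterol synthesis genes were lower for 15 of 19 with a mean of -0.184 (adjusted p = 0.00138, and adjusted p = 0.421 with an estimated correlation), with 0 adjusted over the list alone, HSD17B7 at -0.93 and ACAT2 at -0.35. Zinc transporters were higher for 19 of 21 (adjusted p = 0.011, and adjusted p = 0.421 with an estimated correlation) and 3 passed adjusted over the list alone, with SLC39A1 at 0.50 and MTF1 at 0.35. Immediate early genes were higher for 18 of 21 (adjusted p = 0.011, and adjusted p = 0.421 with an estimated correlation), with 0 adjusted over the list alone and FOSL1, a subunit of the AP-1 transcription factor, at 0.82. Interferon-stimulated genes were higher for 21 of 24 (adjusted p = 0.011, and adjusted p = 0.489 with an estimated correlation), with 0 adjusted over the list alone, IFIT3 at 0.75 and IRF7 at 0.51. The unfolded protein and integrated stress response was lower (adjusted p = 0.0183, and adjusted p = 0.421 with an estimated correlation), with 12 of 24 members below 0, 2 passing adjusted over the list alone, and the amino acid synthesis enzymes PSAT1 at -0.65 and ASNS at -0.60. The respiratory chain was lower for 20 of 27 (adjusted p = 0.0347, and adjusted p = 0.489 with an estimated correlation), with 0 adjusted over the list alone and ATP5PO at -0.24, and it was lost with chip arrays alone (adjusted p = 0.0675). None of the 7 lists passed with fry, with adjusted p from 0.141 to 0.404.

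By limma 0 genes passed in chip TiO2, with 1997 at an unadjusted p under 0.05. The smallest adjusted p were those of SNORD42A (1.13 ± 0.19, adjusted p = 0.0566) and SLC10A5 (1.54 ± 0.28, adjusted p = 0.0618), both of which passed in 5 other settings, followed by TICAM1 (0.94 ± 0.18), AKR1C6P (0.59) and SCN2A (0.64, adjusted p = 0.102), both of the last 2 below the array medians in both groups. Leaving out both replicates 4, which was chosen after seeing the data, gave 73 genes, TiO2 replicate 4 alone gave 23, control replicate 4 alone gave 11, TiO2 replicate 3 gave 2, and TiO2 replicate 1 and control replicate 3 gave 1 each. Array weights gave 1 gene (TICAM1), and the intensity trend, both filters, the deposit batch and the replicate block gave 2.

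No gene passed the test of a difference in TiO2 response between the systems. Here too the concentrations differed, with 100 µg/mL in the chip and 50 µg/mL in Transwell. In simulated data 13.5% of 1.5-fold and 43.5% of 2-fold differences were recovered. By limma 0 genes passed, with 1215 at an unadjusted p under 0.05 and 0 in every setting that kept the adjusted threshold. The genes of smallest p were SLC10A5 (1.88), TCF7L1-IT1 (-1.74), LOC145474 (-2.05), DNM1P41 (-1.11) and SCN2A (0.80), each at adjusted p = 0.708. Immediate early genes had a higher response in the chip (adjusted p = 0.00989, and adjusted p = 0.83 with an estimated correlation), with 0 of 21 adjusted over the list alone, FOSL1 at 1.00 and FOS at 0.59, and cholesterol synthesis a lower one (adjusted p = 0.00989, and adjusted p = 0.83 with an estimated correlation), with 0 of 19 adjusted over the list alone and HSD17B7 at -1.16. Across genes the TiO2 responses in both systems correlated with r = -0.0534 and rho = -0.038.

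**Figure D4:**
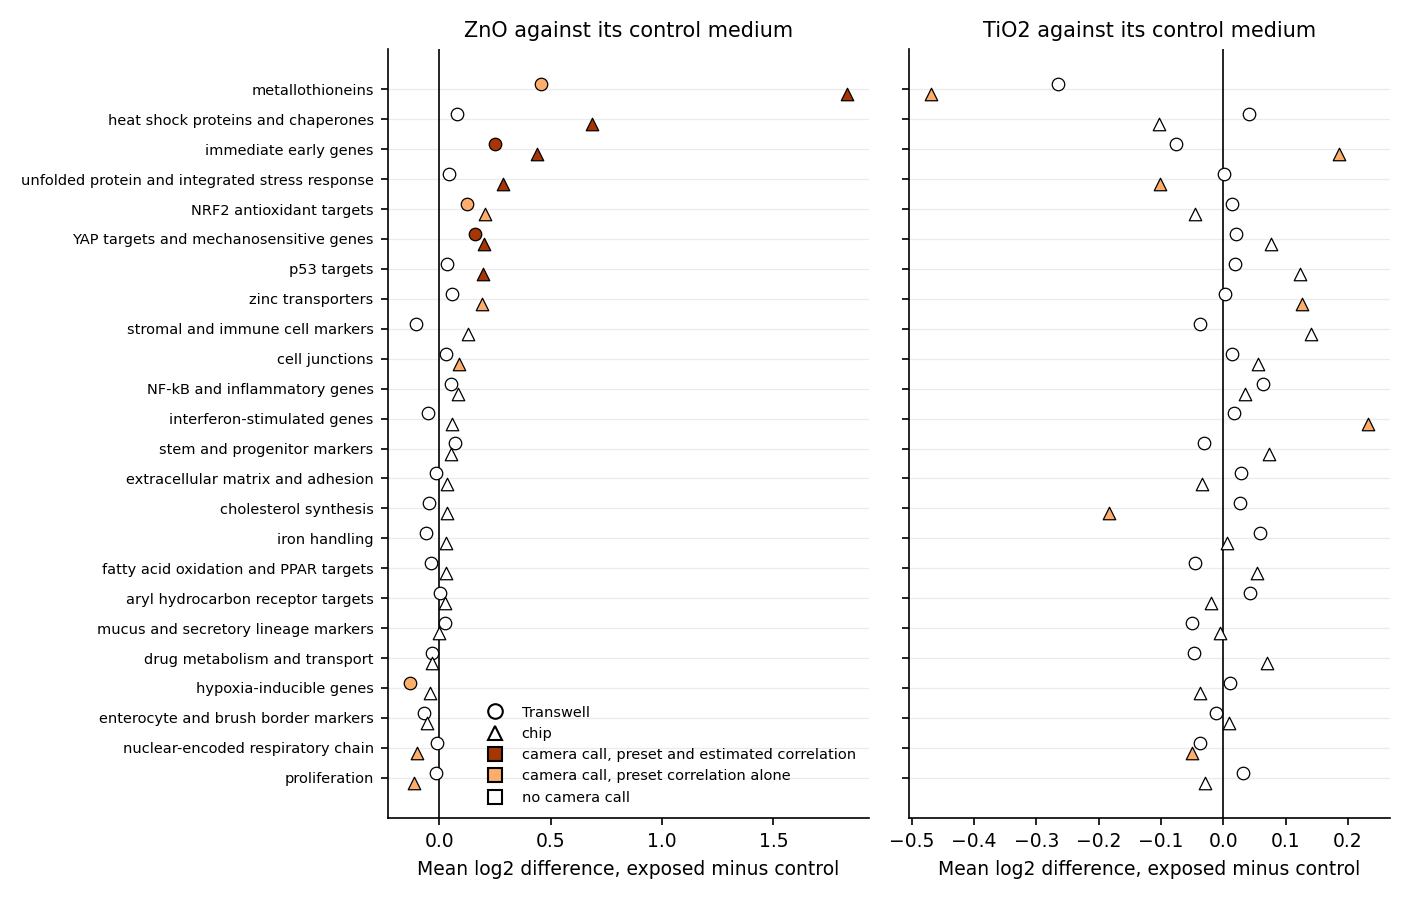
Mean log2 difference between exposed and control arrays over the members of each gene list, with circles for Transwell and triangles for chip, for ZnO and TiO2. Dark symbols passed camera with the preset and an estimated correlation, light symbols with the preset alone and white symbols not at all, and the metallothionein mean after ZnO is 1.83 in the chip and 0.458 in Transwell.

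The last comparison set the ZnO control medium against the TiO2 control medium, over both culture systems. Metallothioneins were higher as a set in the ZnO control medium, and cholesterol synthesis genes and YAP targets were lower. With an estimated correlation YAP targets kept their call (adjusted p = 0.0226), and metallothioneins (adjusted p = 0.303) and cholesterol synthesis (adjusted p = 0.053) lost theirs. MT1X was higher by 1.19 ± 0.12 (adjusted p = 2.71e-06), HMOX1 by 0.98 ± 0.12 (adjusted p = 7.94e-05), TMIGD1, an adhesion protein of epithelial cells, by 0.99 ± 0.17 and the tryptophan dioxygenase TDO2 by 0.96. ERICH4 was lower by -1.37 ± 0.17 (adjusted p = 7.94e-05), the death receptor ligand TNFSF10 by -1.34 ± 0.26, the ubiquitin ligase RNF186 by -1.31 ± 0.22, the collagen crosslinker LOX by -1.06 ± 0.25 and the lipid transfer protein MTTP by -0.99 ± 0.26.

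Of 22395 genes 455 (2.03%) passed, 152 higher and 303 lower in the ZnO control medium, and 120 differed by at least 1.5-fold. Further leading genes were MT1G (1.19), the zinc finger gene ZNF708 (0.82), the metallothionein pseudogene MT1CP (0.84) and 3 small RNA genes among the higher ones, and TMT1A (-1.20), GABRA2 (-1.17), ATP8B2 (-1.15), SLC17A1 (-1.01) and CHI3L1 (-0.97) among the lower ones.

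Cholesterol synthesis genes were lower for 18 of 19 members, of which 9 passed (13 adjusted over the list alone), with a mean of -0.32 (adjusted p = 9.71e-13, and adjusted p = 0.053 with an estimated correlation). STARD4, a sterol carrier, was lower by -0.66, and the synthesis enzymes MSMO1, ACAT2 and SQLE by -0.50, -0.48 and -0.47. YAP targets were lower as a set (adjusted p = 3.41e-05, and 0.0226 with an estimated correlation), with 2 of 19 passing, ANKRD1 at -0.72 and TAGLN at -0.48, and with 8 lower and 1 higher adjusted over the list alone. Their mean was -0.384 in Transwell (adjusted p = 1.22e-06, and 0.00576 with an estimated correlation) and -0.0157 in the chip (adjusted p = 0.891), where 10 of 19 were below 0, and the difference passed (adjusted p = 0.000219, and 0.0449 with an estimated correlation). Hypoxia-inducible genes were lower (adjusted p = 6.75e-06, and adjusted p = 0.389 with an estimated correlation), with 5 of 29 passing (10 adjusted over the list alone), including MXI1 (-0.53) and BNIP3L (-0.44). Their mean was -0.286 in Transwell (adjusted p = 9.71e-06, and adjusted p = 0.339 with an estimated correlation) and -0.097 in the chip (adjusted p = 0.0901). The difference between the systems had adjusted p = 0.0161 (adjusted p = 0.494 with an estimated correlation). Metallothioneins were higher (adjusted p = 5.86e-06, and adjusted p = 0.303 with an estimated correlation), with 3 of 10 passing (5 adjusted over the list alone), MT1X, MT1G and MT2A (0.76). Heat shock genes were higher (adjusted p = 0.000291, and adjusted p = 0.389 with an estimated correlation), with 2 of 16 passing (5 adjusted over the list alone), HSPB1 (0.53) and HSPH1 (0.40). Their mean was 0.628 in Transwell (adjusted p = 3.33e-10, and adjusted p = 0.103 with an estimated correlation) and -0.262 in the chip (adjusted p = 0.00325, and adjusted p = 0.475 with an estimated correlation). With the preset correlation alone NF-kB genes (adjusted p = 0.00855, and adjusted p = 0.389 with an estimated correlation) were lower, with 0 of 26 passing (4 adjusted over the list alone), and so were enterocyte markers (adjusted p = 0.0017, and adjusted p = 0.407 with an estimated correlation), with 2 of 28 passing (2 lower and 1 higher adjusted over the list alone). By system the enterocyte mean was 0.0993 in Transwell, with 16 of 28 members above 0 (adjusted p = 0.536), and -0.474 in the chip (adjusted p = 1.03e-10, and adjusted p = 0.136 with an estimated correlation). Interferon-stimulated genes (adjusted p = 0.0255, and adjusted p = 0.461 with an estimated correlation) were higher over both systems, with 1 of 24 passing, BST2 at 0.37 (1 adjusted over the list alone). Their mean was -0.125 in Transwell (adjusted p = 0.711) and 0.353 in the chip (adjusted p = 1.91e-06, and adjusted p = 0.189 with an estimated correlation). Also higher was the respiratory chain (adjusted p = 0.0148, and adjusted p = 0.389 with an estimated correlation), with 0 of 27 passing (3 adjusted over the list alone).

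Tests of the media by system, here and above, were chosen after seeing the data. The metallothionein difference between the media was larger in Transwell than in the chip with the preset correlation. The list had camera adjusted p = 1.22e-06 in Transwell (adjusted p = 0.249 with an estimated correlation), 0.479 in the chip and 0.000198 for the difference between them (adjusted p = 0.343 with an estimated correlation). Taken by system, MT1X was higher by 2.27 ± 0.17 in Transwell and differed by 0.10 ± 0.17 in the chip, and the difference of these, -2.17 ± 0.24, passed (adjusted p = 1.96e-05). The same test of the difference passed for TMIGD1, with 2.06 in Transwell and -0.08 in the chip (adjusted p = 0.000893), for ANKRD1, with -1.55 and 0.12 (adjusted p = 0.00836), for HSPB1, with 0.94 and 0.12 (adjusted p = 0.049), and for MT1G, with 2.59 and -0.21 (adjusted p = 0.0104). For HMOX1 the values were 1.16 and 0.80, for STARD4 -0.69 and -0.64 and for ACAT2 -0.44 and -0.52, and for none of these 3 did the difference pass. Counted by system, 1486 genes passed in Transwell and 13 in the chip, and 613 genes passed the test of the difference. The chip values here and above include chip TiO2 control replicate 4, which lay apart from its group. Leaving it out raised the count over both systems from 455 to 1036, and the tests by system were not repeated without it. Across genes the medium differences in both systems correlated with r = -0.00797 and rho = -0.0215.

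The count of 455 was 994 with array weights, 803 above log2(20), 294 over every probe set and 277 with the 4 control groups alone. Leaving out chip TiO2 control replicate 4 gave 1036 genes, chip TiO2 control replicates 1, 2 and 3 gave 271, 251 and 252, chip ZnO control replicates 1 and 4 gave 288 and 271, Transwell TiO2 control replicates 2, 3 and 4 gave 234, 290 and 280, and Transwell ZnO control replicates 1 and 2 gave 213 and 254. MT1G, ANKRD1, TAGLN, HSPH1, LOX, MTTP, GABRA2, SLC17A1, ZNF708 and BST2 lost their calls without at least 1 of the 16 arrays, and MT1X, MT2A, HMOX1, TMIGD1, HSPB1, ERICH4, TNFSF10, ACAT2, STARD4, MSMO1 and SQLE did not.

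**Figure D5:**
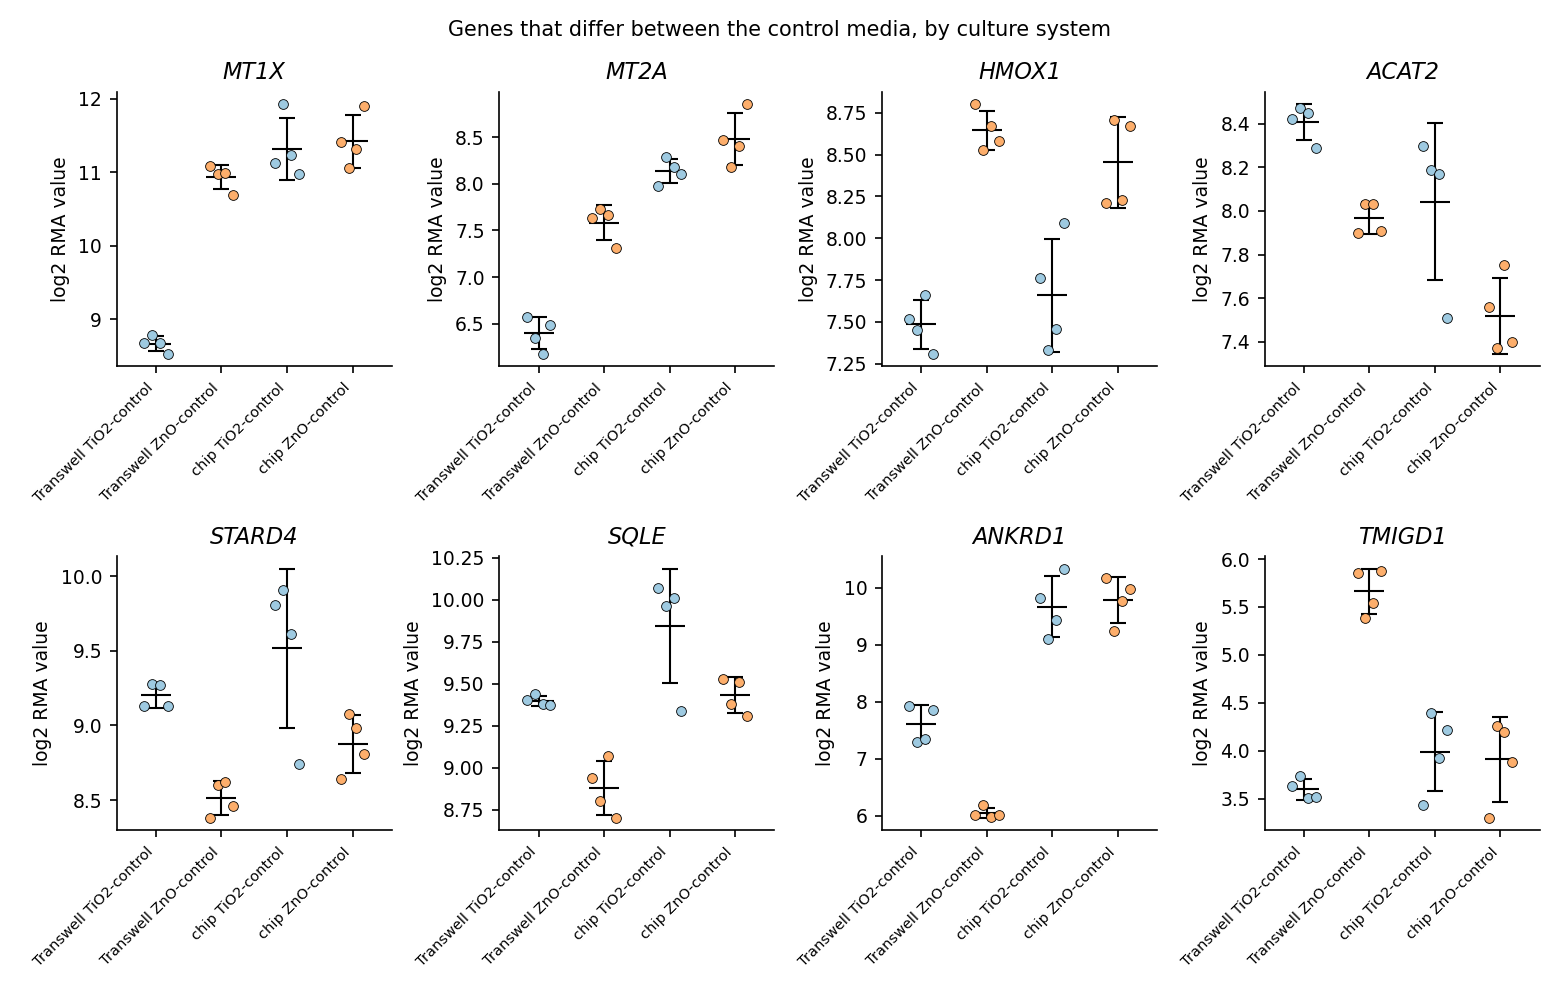
Log2 values of MT1X, MT2A, HMOX1, ACAT2, STARD4, SQLE, ANKRD1 and TMIGD1 in the TiO2 control and ZnO control media of both culture systems, with 1 point per array and bars for the mean ± SD of 4 arrays. MT1X differs between the media by 2.27 in Transwell and by 0.10 in the chip, and STARD4 by -0.69 and -0.64.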

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

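Tests chosen only after the results were seen were those of zinc left in the medium, of exchanged arrays and array quality among the chip ZnO and chip TiO2 arrays, of MT1B and single lists across splits, and the use of counts at an unadjusted p under 0.01 where no gene passed.

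Single arrays stood apart from the other 3 of their group in 10 of 189 groups of values tested, and chance flags about 1 in 20 groups, which is 9.45 here. In Transwell the TiO2 control replicate 1 was high in the mean log2 value of NRF2 targets, at 7.686 against 7.607 to 7.615, and of proliferation genes, at 8.487 against 8.262 to 8.293. Transwell ZnO control replicate 3 was high in the unfolded protein and integrated stress response, at 7.427 against 7.365 to 7.373, and in interferon-stimulated genes, at 4.377 against 4.299 to 4.31. Transwell ZnO control replicate 1 was low in hypoxia-inducible genes, at 7.477 against 7.612 to 7.631. Transwell ZnO replicate 4 was low in iron handling, at 8.165 against 8.272 to 8.29, and Transwell ZnO replicate 3 was low on the first principal component, at -42.25 against -40.48 to -40.12. Chip TiO2 replicate 4 was high in metallothioneins, at 6.456 against 5.645 to 5.721, and low in array weight, at 0.4092 against 0.9964 to 1.037. Chip ZnO control replicate 3 was high in drug metabolism genes, at 7.218 against 6.968 to 6.999. Chip replicates spread more than Transwell replicates, with a ratio of root mean within-group variance of 1.56, and of 1.38 without the 3 chip arrays of lowest weight.

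Several responses differed between the culture systems by a test of the difference. The concentrations also differed, with 80 µg/mL ZnO and 100 µg/mL TiO2 in the chip and 10 and 50 µg/mL in Transwell. For the exposures, system and concentration therefore cannot be told apart. The mean difference in ZnO response, chip minus Transwell, was 1.37 for metallothioneins, 0.607 for heat shock genes, 0.242 for the unfolded protein and integrated stress response, 0.161 for p53 targets, 0.233 for stromal and immune cell markers and -0.0881 for the respiratory chain, and 4.73 for MT1B. None of these lists passed with an estimated correlation, with adjusted p from 0.0767 to 0.712. The mean difference in TiO2 response was 0.263 for immediate early genes and -0.211 for cholesterol synthesis, also lost with an estimated correlation (adjusted p = 0.83). The difference between the control media itself differed between the systems at 613 genes.

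Other splits of the same arrays tested whether the groups mattered. Chance was excluded for chip against Transwell, with 7495 genes against at most 4489 in 100 splits (1 of 100 as large, the real one), and for the control media, with 455 against at most 338 (1 of 100). For Transwell ZnO at an unadjusted p under 0.01 the real split gave the most genes, 178 against at most 172 (median 119.5). Its share, 1 of 35, is the smallest that 35 splits allow and was not adjusted over the comparisons tested. Chance is therefore not taken as excluded here, as 0 genes also passed. The count of 178 was below the 224 expected from uniform p-values, but so was the median of the other splits. The 224 is therefore not the level of chance here. Chance could not be excluded for chip ZnO, with 61 genes against 71 in another split (2 of 35), nor for the difference in ZnO response, with 1 against 2 (7 of 100). At an unadjusted p under 0.01 it could not be excluded for Transwell TiO2, with 107 against 234 (22 of 35), for chip TiO2, with 533 against 1102 (12 of 35), or for the difference in TiO2 response, with 267 against 703 (19 of 100).

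The split of the chip ZnO arrays with 71 genes exchanged ZnO replicate 1 with control replicate 4, and it shared 9 genes with the real split. The array weight of control replicate 4, 1.0139, lay above those of the other 6 arrays (0.663 to 0.966). That of ZnO replicate 1, 0.38528, was the lowest of all 31 arrays. A weight measures only how far an array lies from its group, so it cannot exclude lower quality for either array. An exchange of the 2 arrays cannot be told apart from a wide spread, because over the 159 genes that passed without both ZnO replicate 1 lay at 0.578 and control replicate 4 at 0.505 of the way from the other controls to the other exposed arrays, and over metallothioneins at 0.624 and 0.656. With each array left out alone they lay at 0.474 and 0.56, while control replicate 2 lay at 0.505, the other controls at -0.175 and -0.0111 and the other exposed arrays at 0.667 to 0.951, and the biological explanation, a ZnO response of uneven strength, was not tested apart from these. The smallest limma p of any gene was 3.02e-10 in the real split and 1.21e-07 or more in others. MT1B, picked from the real split, had t = 9.53 against 5.05. List statistics were largest there for metallothioneins (3.97 against 3.72), immediate early genes and the unfolded protein, p53, NRF2 and YAP lists. Cell junctions also led (0.708 against 0.703). Each share, 1 of 35, is the smallest possible, unadjusted over 24 lists. Heat shock genes (3.23 against 3.28), zinc transporters, respiratory chain and proliferation did not lead.

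Metallothioneins differed between the control media in Transwell by a mean of 1.03 log2, and the same list was higher after ZnO in the chip. A single atypical array was excluded, since the difference was at least 0.981 with any of the 8 arrays left out. Zinc left in the ZnO control medium may contribute and was not excluded. The 49 other genes that rose after ZnO in the chip had a median difference between the media of 0.0391 in Transwell and -0.165 in the chip. The bootstrap 95% interval of the Transwell median ran from -0.0226 to 0.215. It resampled genes and not arrays, so it leaves out the spread between arrays. Separate experiments for the 2 nanomaterials cannot be told apart from the medium, because 0 control media were run with both nanomaterials.

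Chip TiO2 replicate 4 and chip TiO2 control replicate 4 lay apart from their groups, and exchanging TiO2 replicate 4 with control replicates 1, 2, 3 and 4 gave 1, 97, 9 and 109 genes past the threshold against 0 in the real split, which points to a structure of these arrays. An exchange of both replicates 4 was not excluded, because over the 73 genes that passed without them the TiO2 array lay at 0.188 and the control array at 0.551 of the way from the other controls to the other exposed arrays. Over the 1075 genes at an unadjusted p under 0.01 without them they lay at 0.287 and 0.594, while the other controls, each left out in turn, lay at 0.348 to 0.424 and the other exposed arrays at 0.651 to 0.726, so the TiO2 array lay on the side of the controls and the control array between the groups. Lower array quality was not excluded either, because the weights of 0.409 and 0.4996 lay below those of the other 6 arrays (0.698 to 1.39), and a weight also falls when an array stands in the wrong group. On the second principal component both arrays lay on the same side, at -15.4 and -9.37. The other chip arrays of the TiO2 set lay at 4.09 to 11.8 there. An exchange alone would leave this common shift in place, and its cause was not tested. The biological explanation, a TiO2 response of uneven strength, was not tested apart from an exchange and array quality.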

How the results depend on the processing

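Settings chosen only after the data were seen were the fit with arrays of the same culture system, the fit with 1 array weight per culture system and the fits without both chip arrays that lay apart. No result reversed in any setting run, and the cause of a change was not tested unless fewer genes or arrays explain it. The 7495 genes of the culture comparison stayed within 1.5 times in 14 of 16 settings, the exceptions being 11318 over every probe set and 3364 with a 1.5-fold minimum, and ran from 7144 to 7530 with 1 array left out. For Transwell ZnO the 0 genes became 5 with array weights, 6 with 1 weight per system and 178 at an unadjusted p under 0.01, and stayed 0 with any array left out. For chip ZnO the 61 genes became 103 with an intensity trend, 25 with array weights, 94 without the lowest 30%, 112 above log2(20), 18 with the replicate block, 15 with 1 weight per system, 37 over every probe set, 699 at an unadjusted p under 0.01, 159 without both ZnO replicate 1 and control replicate 4, 0 with only the groups compared and 1 with only arrays of the same culture system. Leaving out 1 array gave 9 to 144, the lowest without control replicate 3 and the highest without control replicate 4. The adjusted p of MT1B there was 0.0144 with chip arrays alone, and ran from 5.43e-09 to 0.15 over its settings. The difference in ZnO response (1 gene) became 0 over every probe set, 0 with only the groups compared and 282 at an unadjusted p under 0.01, and was 0 to 1 with 1 array left out. For Transwell TiO2 the 0 genes became 107 at an unadjusted p under 0.01. For chip TiO2 the 0 genes became 2 with an intensity trend, 1 with array weights, 2 without the lowest 30%, 2 above log2(20), 2 with the deposit batch covariate, 2 with the replicate block, 73 without both replicates 4 and 533 at an unadjusted p under 0.01, and 0 to 23 with 1 array left out, the highest without TiO2 replicate 4. The difference in TiO2 response became 267 at an unadjusted p under 0.01 and was 0 with any array left out. For the control media the 455 genes became 994 with array weights, 803 above log2(20), 294 over every probe set, 120 with a 1.5-fold minimum, 1418 at an unadjusted p under 0.01 and 277 with only the groups compared, and ran from 213 without Transwell ZnO control replicate 1 to 1036 without chip TiO2 control replicate 4. The correlation of the ZnO responses, 0.0447 over all genes, was 0.527 over genes past the threshold in either system and ran from 0.0168 without chip ZnO control replicate 2 to 0.0814 without chip ZnO control replicate 1. Replicate numbers did not pair the arrays, since 3 of 23 same-numbered pairs correlated over 0.1 (range -0.232 to 0.131) and 5 samples matched their own number best, and the block gave 7435 genes for the culture comparison and 389 for the control media. Of 440 values of genes named for chip ZnO with 1 array left out 310 kept their side of the threshold, 119 lost it and 11 gained it, and of 713 under other settings 561, 134 and 18 did. For the culture comparison all 1136 and 851 such values kept it. With an estimated correlation 40 list tests lost their call. Another 152 kept their side of the threshold, but most of those had no call to lose. With fry 26 list tests lost their call and 8 gained one, and 158 kept their side, most of them again without a call. Signal over background was not used here, so low values were limited only by the filters above.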

Other observations

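All comparisons in this part were chosen only after the values were seen. Those between the control media in the chip include TiO2 control replicate 4, which lay apart from its group, and were not repeated without it.

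Proliferation genes differed between the control media as a set, with means of opposite sign in the 2 culture systems, with the preset correlation alone. In Transwell 28 of 30 members were lower in the ZnO control medium than in the TiO2 control medium, with a mean of -0.356, and 9 of them passed (adjusted p = 6.8e-10, and adjusted p = 0.331 with an estimated correlation). Transwell TiO2 control replicate 1 stood apart in this list, at 8.487 against 8.262 to 8.293, and without it the mean was -0.305 and 3 members passed (adjusted p = 8.74e-07, and adjusted p = 0.372 with an estimated correlation). RRM2, the small subunit of ribonucleotide reductase, was lower by -0.55 ± 0.10 (adjusted p = 0.00117), the spindle checkpoint kinase BUB1 by -0.60 ± 0.15 (adjusted p = 0.017), the cyclin CCNA2 by -0.56 ± 0.15 (adjusted p = 0.0207) and the replication helicase subunit MCM6 by -0.50 ± 0.14 (adjusted p = 0.0249). In the chip 29 of 30 were higher, with a mean of 0.231, and 0 passed (adjusted p = 2.9e-08, and adjusted p = 0.372 with an estimated correlation). The difference between the systems was above 0 for 30 of 30 members, of which 10 passed, with a mean of 0.586 (camera adjusted p = 1.22e-15, and adjusted p = 0.158 with an estimated correlation). Without the same array that mean was 0.535, with 5 members passing (adjusted p = 1.57e-12, and adjusted p = 0.265 with an estimated correlation). RRM2 differed by 0.82 ± 0.14 (adjusted p = 0.00205) and BUB1 by 0.80 ± 0.22 (adjusted p = 0.0426). DDB2, a DNA damage recognition protein and p53 target, was lower by -1.56 ± 0.14 in Transwell and differed by 0.06 ± 0.14 in the chip, and the difference passed (adjusted p = 2.83e-05).

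Heat shock genes also differed. Their mean was 0.628 higher in the ZnO control medium in Transwell, where 8 of 16 passed (adjusted p = 3.33e-10, and adjusted p = 0.103 with an estimated correlation), and in the chip it was -0.262, where 0 passed (adjusted p = 0.00325, and adjusted p = 0.475 with an estimated correlation). The difference between the systems had a mean of -0.89, with 8 of 16 members passing, and the list passed with the preset correlation (adjusted p = 8.37e-12) and with an estimated correlation (adjusted p = 0.0452). HSPH1 was higher by 1.12 ± 0.15 in Transwell and differed by -0.33 ± 0.15 in the chip, with adjusted p = 0.000254 for the difference. In the chip interferon-stimulated genes were higher in the ZnO control medium for 22 of 24 members, with a mean of 0.353 and 0 passing (adjusted p = 1.91e-06, and adjusted p = 0.189 with an estimated correlation), and enterocyte markers were lower for 25 of 28, with a mean of -0.474 and 2 passing (adjusted p = 1.03e-10, and adjusted p = 0.136 with an estimated correlation). The fructose transporter SLC2A5 was lower there by -1.29 ± 0.21 (adjusted p = 0.0185) and MTTP by -1.90 ± 0.37 (adjusted p = 0.047).

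The responses to TiO2 and ZnO in the chip, which had separate controls, correlated across genes with r = 0.191 and rho = 0.187, and the responses in Transwell with r = 0.0364 and rho = 0.0369. Over the 61 genes that passed after ZnO in the chip the correlation was r = -0.311 and rho = -0.101, with 43 of the same sign.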
